A study of Homo sapiens with 2 samples.

How the data were processed

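RNA was sequenced from primary human fibroblasts, connective tissue cells grown directly from a donor rather than an established line. Cells received 1,25D (1α,25-dihydroxyvitamin D3, the hormonally active form of vitamin D) at 100 nM, or serum vehicle. They were collected after 24 h and grown in medium with 10% serum. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into barcoded Ion Torrent libraries, so transcripts without a poly(A) tail are also measured. The data hold 1 library per condition, so no comparison has a replicate check, no p-value or standard error is given between conditions, and differences between the cultures other than 1,25D cannot be separated from it. Whether a library holds a pool of cultures is not stated.

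The authors deposited a single table of 11613 genes with a value for each library and the ratio of the 1,25D value to the vehicle value. The genome build hg19 and bedtools are named in the submitters' processing notes. The aligner, the gene annotation, the strand setting, the normalization and the filter are not given in the sources used here. The unit was therefore read from the values. The deposited values are whole numbers that sum to 261380749 in the vehicle library and to 261389429 in the 1,25D library, a difference of 0.0033%, which raw counts would not give. They were treated as normalised read coverage (a signal per gene), and not as counts. Every gene reaches at least 1000 in at least 1 library, so the table holds only genes past that level. No vehicle value lies between 1 and 29, and 6 genes are listed at 1 in the vehicle library and none in the 1,25D library. The value 1 was read as a stand-in for no coverage, and no fold is given for those genes. The deposited ratio equalled the quotient of the 2 values within 0.00051 in all 11613 rows. It is the authors' comparison and was used here only as an alternative without a pseudocount.

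The sequencing depth in reads is unknown, so no counting interval or detection limit can be given. Whether coverage was divided by gene length is also unknown, so values were compared between libraries within a gene, and not between genes as numbers of transcripts. Reads shared by paralogs or by overlapping genes cannot be told apart in these values.

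The plan had foreseen counts or values such as CPM. The deposited coverage was therefore divided by the library's total and multiplied by 1000000, and the planned settings for normalized values were applied to that scale. The log2 ratio is log2 of the 1,25D value plus 1 over the vehicle value plus 1, both in ppm, which understates the change of genes with low coverage. Genes with at least 5 ppm in the higher library were kept (1307 in deposited units), which left 11155 genes. Folds in the text are on this scale, which is written as ppm (parts of 1000000 of the library's total). X-inactivation and Y-linked genes were left out because the cells come from a donor. A difference of at least 2-fold was counted by size alone.

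To place a single gene, its ratio was ranked among the 500 genes nearest in mean coverage. For gene lists, the median log2 ratio was compared with the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean coverage. A list was called outside when its percentile was below 2.5 or above 97.5. The percentile describes these 2 libraries and treats genes as independent, which co-regulated genes are not. Of 29 lists, 22 had the 5 measured members needed. Symbols were matched directly or through synonyms of the RefSeq gene table of GRCh38.p14. No coordinates are given, because the table holds none and the annotation at hand is of another build than hg19.

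Named genes followed a rule set before the data were examined. It takes the 12 largest and 12 smallest ratios, leaving out unnamed loci, and LMNA, CYP24A1, VDR, RXRA, CYP27B1, BRCA1, TP53BP1 and CTSL1. It adds the 2 highest and 2 lowest members of each list called outside and every vitamin D receptor target at least 2-fold apart. Other list members named in the text were chosen after their values were seen. CYP27B1 was not analysed here, and some genes that the rule takes are not reported here. The gene lists, floor, pseudocount and alternatives were also set then, except where stated.

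The procedure was tested on simulated data built from the real abundances, with ratios shuffled within bins. In that simulation of 1,25D against vehicle on 10955 unchanged genes, 2.5% of 200 random lists of 20 genes were called outside. All 200 lists shifted by 0.5 on the log2 scale were called (100%). Of genes changed 4-fold upward, 100% passed the 2-fold rule, of those changed 2-fold upward 44%, and of unchanged genes 5.33%. The unchanged genes keep the observed ratios, shuffled, so 5.33% reflects the spread between these 2 libraries, not a false-call rate. Shuffling also removes co-regulation, so the 2.5% need not hold for lists of co-regulated genes. The shift of 0.5 is larger in size than the median of every list called outside except the receptor targets. Alternatives were pseudocounts of 0.1 and 5, floors of 0 and 20 ppm, centring on the median gene, a trimmed mean of M-values (trim 30% of ratios and 5% of abundances, unweighted), totals without the 20 most abundant genes, and lists or genes left out. Alternatives based on counting intervals were not run, since no counts are known. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. GC content and length came from GENCODE 29 transcripts, the longest per gene, and were found for 97.97% of the genes kept.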

Results

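The transcriptome of primary human fibroblasts was compared between a culture given 100 nM 1,25D for 24 h and a culture given serum vehicle. The series' title names the gene LMNA, which encodes lamins A and C of the nuclear lamina, as the gene whose regulation by vitamin D and its receptor is under study. The vehicle library had a total normalised coverage of 261380749 and the 1,25D library 261389429. Fibronectin (FN1) took the largest part, with 4.14% of the vehicle total and 4.36% of the 1,25D total. The 20 most abundant genes of each library took 20.96% and 22.55%. Each condition had 1 library, so none of the values below carries an error and none of the differences has been tested against replicate spread.

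Fibroblast and matrix genes were abundant in both libraries. COL1A1, the main type I collagen chain, had 23183 ppm (parts of 1000000 of the library's total normalised coverage) in the vehicle library and 33144 with 1,25D, and vimentin (VIM) had 8116 and 6667. The 15 fibroblast markers had a median log2 ratio of -0.14, at percentile 24.2 of matched random lists. Of the markers of other cell types, few were in the table: 3 of 13 for keratinocytes, 2 of 10 for endothelium, 1 of 12 for leukocytes, 1 of 8 for melanocytes, 5 of 9 for smooth muscle and pericytes, and 1 of 8 for adipocytes. At a pseudocount of 1, the largest difference among those above the floor was in desmoplakin (DSP), a desmosomal protein. It had 1142 ppm in the vehicle library and 2516 with 1,25D. The leukocyte marker in the table, the lysosomal protein CD68, had 63.95 and 97.83 ppm. The endothelial receptors went opposite ways, with TEK at 10.4 and 4.59 and FLT1 at 4.71 and 9.46.

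The largest difference in the table was in CYP24A1, the 24-hydroxylase that inactivates 1,25D and the textbook target of the vitamin D receptor. It was listed at 1 in the vehicle library, the value standing for no coverage, and at 501412 (1918 ppm) in the 1,25D library. No fold can be given for it. The next at a pseudocount of 1 were LGALS9 (galectin-9), 28.9-fold higher with 1,25D, TGFB2 (transforming growth factor beta 2), 23.5-fold higher, and CYP26B1, a retinoic acid hydroxylase, 20.6-fold higher. LGALS9 has near-identical gene copies, so its coverage is uncertain. CILP, a cartilage matrix protein, was 20.4-fold higher, the thrombin receptor thrombomodulin (THBD) 18.5-fold, and the p38 delta kinase MAPK13 13.6-fold. The cytokine IL16 had 2.91 ppm in the vehicle library and 45.8 with 1,25D. EXPH5, a RAB27 effector, was 11.7-fold higher. The elongation factor EEF1A2, a close paralog of the abundant EEF1A1, was 10.9-fold higher. SERINC2, a serine incorporator, was 10.7-fold higher and reached 471 ppm, from 43.0 in the vehicle library. The folds and their order depend on the pseudocount where the vehicle value is low, as for LGALS9 (0.79 ppm) and CILP (1.09 ppm). In the authors' deposited table, the ratio was 64.4 for LGALS9, 38.2 for CILP, 31.1 for TGFB2 and 22.4 for CYP26B1.

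In the other direction, at the same pseudocount, the ubiquitin ligase RNF182 was 8.23-fold lower with 1,25D and the cAMP phosphodiesterase PDE4D 8.13-fold lower. The pseudokinase TRIB2 was 7.36-fold lower, the receptor phosphatase PTPRB 7.12-fold, the zinc finger protein BNC1 6.79-fold and filaggrin (FLG) 6.64-fold. KRTAP1-5, of a multigene family of hair keratin-associated proteins, was 6.62-fold lower. GPRC5A, an orphan receptor known as inducible by retinoic acid, was 5.79-fold lower. PPP1R3C, which brings protein phosphatase 1 to glycogen, was 5.40-fold lower, from 89.9 to 15.8 ppm. The ligand EFNB2 was 5.37-fold lower, KIAA1383 5.25-fold and the methyltransferase METTL21D 5.19-fold. Except for PPP1R3C, TRIB2 and KRTAP1-5, these genes had under 20 ppm in the vehicle library. With 1,25D, all but PPP1R3C had under 5 ppm, so their folds and order also depend on the pseudocount. In the authors' deposited table, the ratio was 0.068 for RNF182, 0.037 for PDE4D and 0.045 for KIAA1383.

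Of 11155 genes, 414 were at least 2-fold higher with 1,25D and 368 at least 2-fold lower. Without genes listed at 1 the higher count was 411. At 4-fold the counts were 63 and 28, and at 8-fold 19 and 2, all at a pseudocount of 1. That pseudocount shrinks ratios where a value is low, so these counts and their balance depend on it. PTPRB, for example, was 7.12-fold lower at this pseudocount, while its ratio in the authors' deposited table was 0.088. Counts at 4-fold and 8-fold were not made at other pseudocounts. Centring the ratios on the median gene (log2 ratio -0.08) gave 509 higher and 286 lower, so the higher genes made up 64.0% of these in place of 52.9%. The trimmed mean scaling gave 63.4%. The spread of ratios depended on coverage: with genes divided by coverage into 10 equal groups, 0.5 times the distance between the 16 and 84 percentiles was 0.89 on the log2 scale in the lowest group and 0.29 in group 9. In group 10, the most abundant, it was 0.38. The lowest group alone held 151 of the 414 higher and 127 of the 368 lower genes. Among the 1618 genes with a mean of at least 100 ppm, 44 were at least 2-fold higher and 17 at least 2-fold lower.

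**Figure D1:**
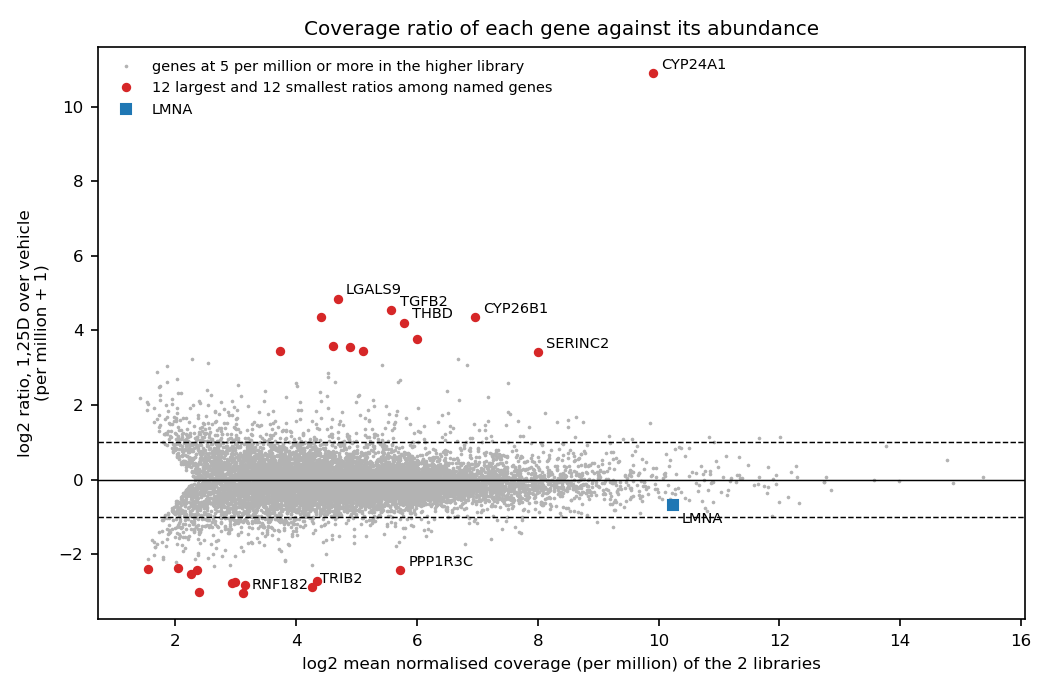
Log2 ratio of 1,25D over vehicle (ppm plus 1) against the log2 mean coverage of the 2 libraries, one grey point per gene, with the 12 largest and 12 smallest ratios in red, LMNA as a blue square and dashed lines at 2-fold. The points spread more widely at low coverage, and the height of CYP24A1 depends on the pseudocount because its vehicle value stands for no coverage.

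Genes known as targets of the vitamin D receptor were higher with 1,25D as a group. Of 32 genes on the list, 23 were measured, 17 had a higher value with 1,25D and 12 were at least 2-fold higher, while 1 was at least 2-fold lower. The list's median log2 ratio of 1.01 lay above all 10000 matched random lists, whose central range ran from -0.29 to 0.14. The higher genes include CYP24A1 and G0S2, whose ratios depend on the pseudocount because both were listed at 1. Without them the median was 0.99 (percentile 100, 21 genes). Beside CYP24A1 and THBD, the MAP kinase phosphatase DUSP10 was 6.17-fold higher, the semaphorin SEMA3B 6.16-fold, and CD14, the lipopolysaccharide co-receptor, 6.02-fold. The membrane protein NINJ1 had 13.6 and 63.3 ppm. EFTUD1, a ribosome maturation factor, was 4.37-fold higher and SEMA6D 4.24-fold. Osteopontin (SPP1) was 2.66-fold higher, GADD45A, a stress-response gene, 2.08-fold and the transcription factor CEBPB 2.01-fold. G0S2, a lipolysis inhibitor, was listed at 1 in the vehicle library and at 6.48 ppm with 1,25D. The transcription factor CEBPD was 2.48-fold lower (7.45 against 2.41 ppm), at the 5.8 percentile of its 500 neighbours in coverage. The nuclear receptor PPARD was 1.62-fold lower.

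VDR and RXRA differed less than these targets. VDR, the vitamin D receptor itself, had 158 ppm in the vehicle library and 181 with 1,25D, a 1.14-fold higher value at the 78.0 percentile of its 500 neighbours. RXRA, its heterodimer partner, had 85.6 and 70.1 ppm, at the 23.6 percentile. The 16 measured genes of vitamin D metabolism, receptors and coregulators had a median log2 ratio of -0.06, at percentile 58.5 of their random lists. They include CYP24A1, and CUBN, a receptor for protein-bound vitamin D uptake, was 2.31-fold lower; the other members differed by less than 2-fold. Without CYP24A1, which was listed at 1, the median was -0.11 (percentile 40.5).

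LMNA was lower with 1,25D. Its coverage was 1490 ppm in the vehicle library and 936 in the 1,25D library, a 1.59-fold lower value and a log2 ratio of -0.67. Of the 500 genes nearest in coverage, 4.8% had a ratio lower still. Over 6 alternatives (3 of scaling and 3 of pseudocount), the log2 ratio ranged from -0.67 to -0.59. A pseudocount hardly moves a gene at this coverage, and the scalings shift all genes alike, by 0.03 to 0.08. The narrow range was therefore fixed in advance and says little about how reliable the ratio is. Among the other lamina genes, the lamin B receptor LBR had 29.2 and 14.8 ppm, LMNB2 (lamin B2) 249 and 164, and LMNB1 (lamin B1) 50.3 and 40.8. The nuclear pore protein NUP153 was 1.64-fold lower, and emerin (EMD) had 35.9 and 23.9 ppm. The LINC complex proteins SUN1 and SYNE2 had higher values with 1,25D, by 1.46-fold and 1.38-fold. Of 24 measured lamina and envelope genes, 15 were lower and 9 higher with 1,25D and none differed 2-fold. The list's median of -0.15 lay at percentile 21.9, inside the range of random lists, so the list as a whole did not stand apart.

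**Figure D2:**
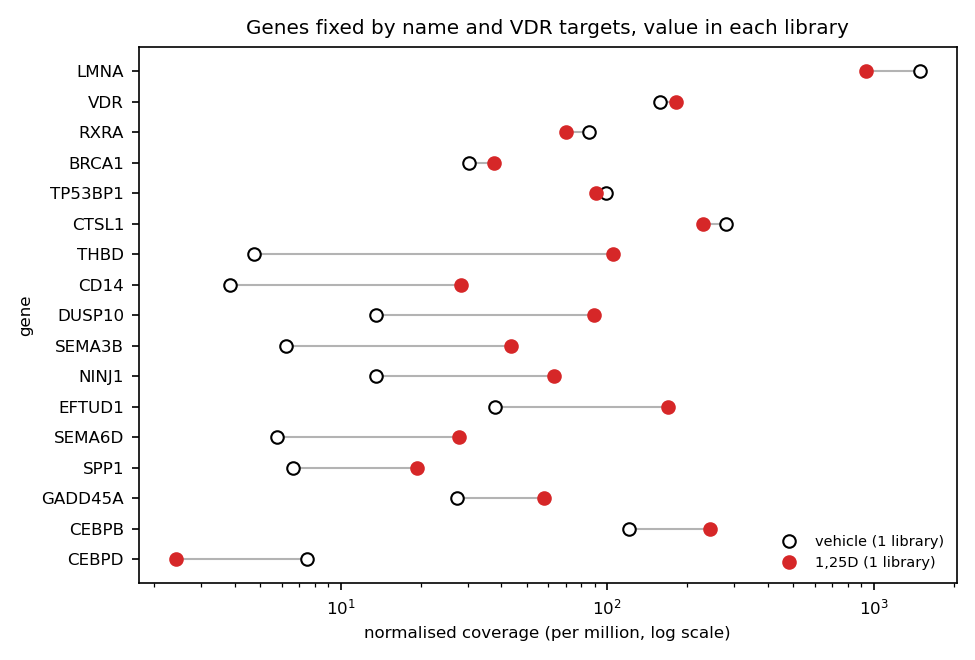
Normalised coverage ppm on a log axis for genes fixed by name and vitamin D receptor targets at least 2-fold apart, with an open circle for the vehicle library, a filled red circle for the 1,25D library and a line joining them. LMNA lies lower with 1,25D (936 against 1490 ppm), and the targets lie higher except CEBPD; CYP24A1 and G0S2 are left out because their vehicle value stands for no coverage.

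DNA repair genes did not stand apart as a list. The 28 measured members had a median log2 ratio of -0.14, at percentile 26.1, and none differed 2-fold. BRCA1, which acts in homologous recombination, was 1.24-fold higher with 1,25D (30.3 against 37.8 ppm), at the 85.6 percentile of its neighbours. TP53BP1, which acts in end joining, was 1.10-fold lower, at the 46.0 percentile. The cathepsin list also holds other lysosomal genes and the protease inhibitors CST3 and CSTB. Its members had higher values: 12 of 15 were higher with 1,25D, with a median log2 ratio of 0.25 at percentile 99.6. CST3 was among the 12 higher and CSTB among the 3 lower. Cathepsin F (CTSF) was 1.74-fold higher and legumain (LGMN) 1.53-fold. CTSL1 (cathepsin L) and CTSZ (cathepsin Z) went the other way, 1.22-fold and 1.13-fold lower. None of these differed 2-fold.

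Of the 22 lists, 6 lay outside the central range of their random lists, where 1.1 would by chance if genes within a list were independent. Co-regulated genes are not independent, so chance could give more than 1.1. Beside the receptor targets and cathepsins, the 6 lists were matrix turnover, cholesterol, cell cycle and immediate-early genes. Matrix proteases and inhibitors had a median log2 ratio of 0.24 (percentile 99.6), with the stromelysin MMP3 at 1296 and 2597 ppm and the collagenase MMP1 1.56-fold higher. The inhibitor TIMP3 was 1.95-fold lower, from 4997 to 2557 ppm, and the protease ADAMTS1 1.58-fold lower. Cholesterol genes had a median of 0.10 (percentile 98.0). Of 22 measured, 14 were higher and 8 lower. The members that were highest are transport proteins, STARD4 at 3.39-fold and NPC1 at 2.17-fold higher. Genes of the synthesis pathway went both ways, with MVD 1.30-fold higher and IDI1 1.24-fold lower.

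Cell cycle genes had a median log2 ratio of -0.25 (percentile 1.28). Of 32 genes, 25 were lower with 1,25D and none reached 2-fold. The mitotic kinase AURKB was 1.57-fold lower and the kinesin CENPE 1.56-fold lower, while E2F1 was 1.30-fold and CCNE2 1.21-fold higher. Replication-dependent histones, which are made in S phase, had a median of -0.17 at percentile 23.6. Immediate-early genes had the lowest median, -0.37 (percentile 0.28), and 14 of 19 were lower with 1,25D. IER3 was 4.85-fold lower and KLF2 3.08-fold lower, and JUNB had 53.4 ppm in the vehicle library and 18.1 with 1,25D. In the other direction, ZFP36, which promotes decay of AU-rich transcripts, had 79.5 and 199.8 ppm and the phosphatase DUSP1 was 1.48-fold higher. At a floor of 20 ppm the immediate-early list (percentile 5.11) and the matrix turnover list (96.6) no longer lay outside. The cell cycle list reached percentile 2.74 against unmatched random lists, and the cholesterol list lay inside under 3 alternatives (95.8 to 97.3).

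The other lists lay inside their random ranges. Structural matrix genes had a median log2 ratio of -0.14, with the cross-linking enzyme LOX at 2576 and 5664 ppm and periostin (POSTN) at 2299 and 1289. TGF-beta response and contractile genes had a median of -0.01, inflammatory genes -0.03, interferon-stimulated genes 0.04, and p53 and senescence genes -0.02. Of 13 inflammatory genes, 6 were higher and 7 lower. The neutrophil-attracting chemokines CXCL1 (8.60 against 1.97 ppm), CXCL5 (7.12 against 1.78) and CXCL6 (5.80 against 2.26) were lower, all at low coverage. They lay at the 1.6, 3.4 and 15.4 percentiles of their neighbours in coverage, so CXCL6 did not stand apart. CXCL12 had 224 and 357 ppm. Stress genes of the endoplasmic reticulum and heat response had a median of -0.19, NRF2 targets 0.00, glycolysis and hypoxia genes -0.19, nuclear respiratory chain genes -0.09 and ribosomal proteins 0.00. Calcium and bone genes had a median of 0.13 (percentile 93.1), and 4 of 13 were at least 2-fold higher: SPP1, the calcium-regulating hormone stanniocalcin 1 (STC1) at 6.38-fold, alkaline phosphatase (ALPL) at 4.21-fold and BMP6 at 2.58-fold.

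**Figure D3:**
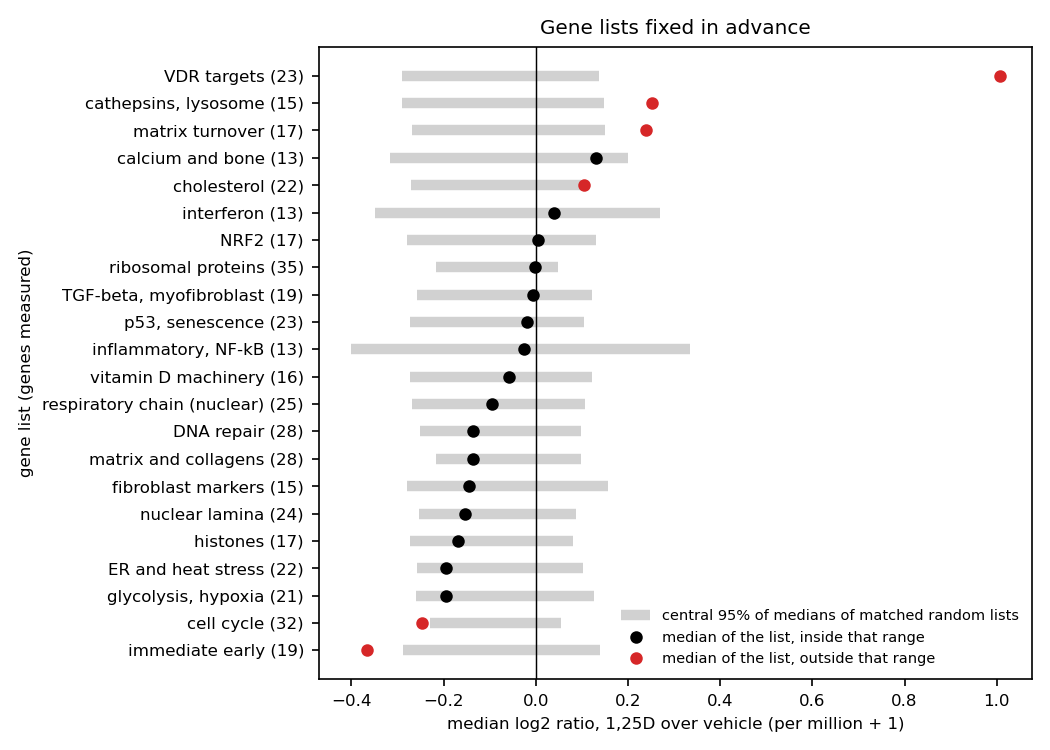
Median log2 ratio of 1,25D over vehicle for each of 22 gene lists (number of genes measured in parentheses), with grey bars for the central 95% of the medians of 10000 matched random lists and red points for lists outside them. The vitamin D receptor targets lie at 1.01, far from the other lists, which run from -0.37 to 0.25.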

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

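No library can be left out, because each condition has 1, and depth in reads is unknown, so genes with low coverage carry the least weight. Counts of genes depended on the pseudocount and the floor: a floor of 20 ppm gave 187 higher and 124 lower genes in place of 414 and 368, and a pseudocount of 5 gave 196 and 111. The floor leaves fewer genes to count and the pseudocount shrinks low ones. The CYP24A1 log2 ratio is set by the pseudocount, because its vehicle value stands for no coverage: it was 10.9 with 1, 14.17 with 0.1, 8.59 with 5 and 18.94 in the authors' deposited ratio. Under 3 scalings and 3 pseudocounts the LMNA log2 ratio lay between -0.67 and -0.59. Its high coverage and shifts common to all genes fixed this narrow range in advance. Of 158 list medians under settings that can move them, 148 moved by less than the SD of their random lists. The scalings shift all ratios by 0.03 to 0.08, less than most of these SDs, so most medians under them could hardly count as moved. With a floor of 20, which leaves fewer members, the medians were 1.57 for receptor targets, 0.12 for NRF2 targets, -0.19 for calcium and bone genes, 0.40 for inflammatory genes (percentile 98.1, on 5 genes), -0.27 for interferon genes and 0.105 for p53 genes. Centring on the median gene put cell cycle genes at -0.17 and ribosomal proteins at 0.076, and the trimmed mean scaling at -0.17 and 0.076; both shift the ratios of all genes by about 0.08, and centring leaves a list's percentile as it was by construction. Without a floor, the calcium and bone list moved outside (0.26, percentile 99.4). Of 354 values of other named genes under the scalings and pseudocounts, 304 moved by less than the spread of their neighbours and 50 by more. All 50 were under another pseudocount or none. The shift by the scalings is smaller than each of these spreads, so no value under a scaling could count as moved. The 304 therefore say little about how reliable the ratios are. The alternatives without a pseudocount and without genes listed at 1 were chosen after seeing the data.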

Other observations

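The retinoid, ligand, WNT and small nucleolar RNA groups and the tests of GC content, ERK output, short-lived RNA and size selection were chosen after the ratios were seen, so they are not independent evidence. The trimmed mean scaling was planned, but its bound for LMNA was set after the value was seen. Retinoid genes held several of the larger differences. CYP26B1, which degrades retinoic acid, had 10.6 ppm in the vehicle library and 238 with 1,25D. RDH10, which makes retinal from retinol, had 126 and 337, the receptor RARA 37.1 and 92.4, and the retinoid-inducible chemoattractant RARRES2 (chemerin) 9.09 and 29.1. The retinal reductase DHRS3 (106 and 36.5) and the retinoic acid binding protein CRABP2 (53.1 and 23.3) were lower. Of 14 measured genes, 4 were at least 2-fold higher and 2 at least 2-fold lower, and the median log2 ratio was 0.27 (percentile 99.8). GPRC5A, known as inducible by retinoic acid and 5.79-fold lower with 1,25D, was not on this list.

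Single ligand genes of several growth factor families differed by 2-fold or more, while the ligand and WNT lists as a whole lay inside their random ranges. Of 18 genes for TGF-beta, activin and BMP ligands and their binding proteins, 5 were at least 2-fold higher and none 2-fold lower (median 0.14, percentile 96.6). They were TGFB2, TGFB3 (7.37 and 19.8 ppm), INHBB (0.34 and 7.77), BMP6 and NBL1 (439 and 929). Of 14 ligands of the PDGF, FGF, VEGF and related families, 3 were at least 2-fold higher and 4 at least 2-fold lower (median -0.01, percentile 73.7). Placental growth factor (PGF, 10.7 and 54.9), VEGFA (54.2 and 133) and FGF9 (3.24 and 11.3) were higher, and PDGFC (78.2 and 22.0), PDGFA (6.99 and 1.73), FGF7 (100.4 and 38.8) and FGF1 (20.4 and 9.43) were lower. Of 25 WNT pathway genes, 5 were at least 2-fold lower and 1 at least 2-fold higher (median -0.08, percentile 46.6), with WNT5A at 226 and 74.7 and its receptor ROR1 at 33.7 and 9.86.

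LMNA coverage was lower in the 1,25D library, by -0.67 on the log2 scale. The tables argue against a trend of the ratio with GC content: the 200 abundant genes nearest to its GC content of 61.5% had a median log2 ratio of -0.001, and 7 of them had a lower ratio than LMNA. Trimmed mean scaling shifts all genes by 0.078 on the log2 scale, which put LMNA at -0.593. A scaling difference of that size is not the whole cause, but this scaling cannot detect a shift of most genes together. Also open is culture-to-culture variation unrelated to 1,25D, because no pair of vehicle cultures is at hand. The only value bearing on it is that LMNA lay at the 4.8 percentile of its neighbours in coverage, so an effect of 1,25D and such variation cannot be told apart.

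Immediate-early genes were lower in the 1,25D library. Lower ERK pathway output could be a hypothesis, since the ERK-induced genes PHLDA1 (107 and 24.5 ppm) and SPRY4 (81.1 and 39.1) were lower too. The median of 11 ERK output genes outside the list was 0.01, however (percentile 78.45). Of them, 6 were higher and 5 lower, with 0 at least 2-fold higher and 2 at least 2-fold lower. Immediate-early members were left out of this test. Among those, DUSP6 (42.1 and 21.6 ppm) and DUSP5 (22.4 and 11.6) were lower and DUSP1 (234 and 347) higher. A loss of short-lived RNA in general was tested on 26 other transcripts of that kind, whose median was 0.04 (percentile 93.21). Neither median was low among its random lists, but the members of both lists spread too widely (0.69 and 0.49 on the log2 scale) to exclude either explanation.

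Small nucleolar RNAs, which guide modification of ribosomal RNA, were higher in the 1,25D library. Of 235 measured, 160 were higher, and the median log2 ratio of 0.17 lay above all matched random lists. Higher coverage of the host genes, in whose introns most of them lie, is argued against by the median of 95 annotated host genes, -0.124. That median lies under that of the small RNAs by more than the spread of the hosts (0.30 against 0.26). In addition, 127 of 164 pairs had a higher ratio for the small RNA than for its host. Small RNAs can share a host, so the pairs are not independent. Size selection that kept more short RNA stays open. The 19 other genes annotated as short non-coding RNA, many of them microRNA entries, had a median of -0.177. Of these, 9 were higher and 10 lower, and their spread of 0.48 exceeds the gap of 0.35. Their coverage may also include reads of overlapping genes, which cannot be told apart. An effect of 1,25D on this class, and of depletion or fragmentation, was not tested.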
